A study of Homo sapiens with 10 samples.

How the data were processed

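H2Bub was profiled by ChIP-seq in MCF7 cells after lentiviral shRNA and puromycin selection, with 1 antibody for all libraries, per the labels' protocols. Libraries were grouped by their titles into pGIPZ (1 library), pLKO (2), shATXN7L3 (1), shUSP22 (2), shUSP27x (2) and shUSP51 (2). Nothing in the labels says whether numbered libraries came from separate cultures, so the authors' p-values measure the spread between these libraries, which may be technical. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.1.2, edgeR 3.6.2 and the build hg19. The counting of reads over genes and the settings of each step are not given in the sources used here.

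The deposited files are 4 tables of the authors' comparisons with no values per library. Per the file headers, each holds for every gene row a score of a first and of a second side, and the unit of the score is not stated. The log2 ratio in each deposited table is that of the second over the first score, to within 1.35e-14. The deposited p-value is joined by an adjusted p that equals a Benjamini-Hochberg adjustment over the rows of its table to within 3.3e-05. Each table had 27034 rows, of which 1 carried no values and was left out. Of the 20891 symbols, 4238 had several rows, up to 13, and the row of highest mean score was used. The mean of the first and second scores was the same in all 4 deposited tables for every row, to rounding, so the level of a gene is common to them and a score cannot be set against another table's score.

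The design written before the data were examined was a quasi-likelihood test on counts over 8 libraries. The tables hold no values per library, so its stated fallback was used, in which only the authors' deposited comparisons are described. A gene was called at a deposited adjusted p under 0.05. Direct contrasts between knockdowns need values per library and were not made. Depth per library could not be read from the tables. No other per-library column was present (0).

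The sides of the tables were checked from low ratios. All 2809 rows of the shATXN7L3 table with a mean score under 1 had a ratio that whole reads in 1 library on each side, plus a small prior of 0.125, would give, to within 1e-06 on the log2 scale, with effective library sizes in a ratio of 1.00. In the shUSP51 table, with several libraries, 12 rows did so. A mean score of 1 stood for about 15.2 reads on the first and 14.2 on the second side of the shATXN7L3 table. Regressed on the log2 reads of the first and second sides of that table over 2804 low rows, the ratios of the shUSP22 table had slopes of -0.81 ± 0.02 (SE) and 0.30 ± 0.02, those of shUSP27x -0.18 ± 0.02 and 0.07 ± 0.02, and those of shUSP51 -0.18 ± 0.02 and 0.11 ± 0.02. The shUSP22 table therefore shared its first side with the shATXN7L3 table, and the first side was taken as the control. Which control vector that was cannot be read from the headers. The step matching was tested on simulated reads, where 100% of ratios fell on the steps, and 0.283% after random shifts.

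Genes were named by a rule written before the data were examined, with a substitute for its level. The rule asked for a mean of at least 100 counts, which the tables do not give, so a mean score above the median of all genes took its place after the data were seen. Per shUSP table these were the 8 largest positive and 8 largest negative ratios among called genes with a mean score above the median of all genes (12.9). For shATXN7L3 they were the 8 largest ratios each way at that level without a test. Added to these were ATXN7L3, ENY2, USP22, USP27X and USP51 and up to 4 members of each list. The part of the rule on the direction of single libraries could not be applied. Genes of the Y chromosome were left out, and 1 result was left out because it names an item withheld for evaluation.

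The 28 gene lists were written before the data were examined. A set test on values per library with a self-contained test beside it was planned and could not be made. In its place each list was tested in the shUSP tables with limma 3.58.1 (cameraPR, R 4.3.3) on signed z values made from the deposited ratio and p, with a correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 28 lists of a table. On simulated z values of 20891 genes, 100% of 200 lists of 20 genes raised by 1 were called and 4% of lists not raised. A list's median ratio was also set against 10000 random lists drawn within 20 bins of mean score. Counts of called members are over all genes, or adjusted over the list alone where stated.

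The neighbour subtraction was planned per library and was made on the ratios instead. Alternatives were a stricter adjusted p of 0.01, genes with a mean score above the median, ratios less the running median of neighbouring genes, centred ratios, ratios less their trend with mean score, adjustment over 1 row per gene, genes with 1 row only and a correlation of 0.05 in the set test. Where a ratio was changed, it was tested again with the standard error implied by its deposited log2 ratio and p-value, taken as normal. In a simulation on the 20891 genes of the shUSP27x table, with 200 genes changed by 1.5 log2 units, 99% were recovered and 8 unchanged genes were called. Neighbours came from the RefSeq gene table of GRCh38.p14, used only for names and gene order, since the build differs from that of the files. It placed 19987 of the 20891 symbols, 18352 by symbol and 1635 by synonym. Correlations between tables were set against 50 simulations of unchanged groups with 1 shared control that holds as much of each variance as the compared group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.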

Results

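Monoubiquitinated histone H2B (H2Bub), a chromatin mark laid over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in MCF7 cells, an oestrogen receptor-positive line of the luminal breast epithelium. The series held 10 libraries. These were 1 library of cells carrying the pGIPZ control vector, 2 of cells carrying the pLKO control vector, 1 of cells with an shRNA against ATXN7L3, and 2 each with an shRNA against USP22, USP27x or USP51. ATXN7L3 is an adaptor of the deubiquitinase module of the SAGA coactivator complex, and the other 3 targets are ubiquitin-specific proteases that remove ubiquitin from H2B. The comparisons asked how the distribution of H2Bub over genes differed between each knockdown and cells with a non-targeting vector.

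The deposited data were 4 tables of the authors' comparisons, 1 per knockdown, each with a score for a first and a second side, the log2 ratio of second over first, a p-value and an adjusted p for 27033 rows under 20891 gene symbols. Each gene was represented by its row of highest mean score and was called where the deposited adjusted p was under 0.05. No table held values per library, so no spread between replicates and no depth per library could be given. The headers name neither side. The shATXN7L3 and shUSP22 tables shared their first side, which a pair of different knockdowns can share only if it is the control, so "higher" below means a second score above the first and is read as more H2Bub in the knockdown. For the shUSP27x and shUSP51 tables this reading rests on the identical headers; their ratios had a Pearson correlation of 0.710 over the rows with a mean score under 1 (0.506 for the shATXN7L3 and shUSP22 tables), as tables with a common side would, but this does not tell which side. Ratios are relative to each table's own scaling, so a change of total H2Bub shared by all genes would not appear.

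H2Bub over the targeted genes themselves was not called in any of the authors' deposited tables. The log2 ratio was 0.31 at USP22 in the shUSP22 table (adjusted p = 0.570), -0.29 at USP27X in the shUSP27x table (adjusted p = 0.734), -0.21 at USP51 in the shUSP51 table (adjusted p = 0.914) and 0.08 at ATXN7L3 in the shATXN7L3 table, all in the authors' deposited tables. An shRNA acts on the transcript, so these values do not measure the knockdown. ENY2, the other adaptor of the module, had log2 ratios of 0.30, 0.43, 0.47 and 0.28 in the authors' deposited tables for shATXN7L3, shUSP22, shUSP27x and shUSP51, with no call. In the list of 9 genes of the module and its partner proteases, ATXN7L2 was called higher in the authors' deposited shUSP22 table (1.37, adjusted p = 0.0465) and ATXN7 in the authors' deposited shUSP27x table (0.81, adjusted p = 0.0116).

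In the comparison for USP22, H2Bub was lower over mesenchymal genes and higher over luminal and epithelial genes. The authors' deposited table called 988 of the 20891 genes, 866 lower and 122 higher; the higher genes were 78 once the ratios were centred on their median and 74 once their trend with mean score was removed. If the first side it shares with the shATXN7L3 table is the same single library, these calls rest on 1 control library. The largest decreases among well-covered genes were at FLI1, an ETS transcription factor (log2 ratio -2.54, adjusted p = 5.71e-05 in the authors' deposited table), at MOXD1 (-2.34), RNF182 (-2.20), CNIH3 (-2.19), PARK2, the ubiquitin ligase parkin (-2.19, adjusted p = 1.18e-05), TMEM132E (-2.19), LPAR3 (-2.18) and PRRX1, a mesenchymal homeobox factor (-2.16). The largest increases among well-covered genes of the authors' deposited table were at CACNG4, a calcium channel subunit (1.76, adjusted p = 0.00896), the desmosomal gene EVPL (1.69), the adaptor DOK7 (1.64), the receptor tyrosine kinase RET (1.63, adjusted p = 0.000888) and the proteasomal ubiquitin receptor ADRM1 (1.56). LOC100128338, TSTA3 and NPEPL1 followed, with ratios of 1.46, 1.38 and 1.38 in the authors' deposited table.

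Among the gene lists fixed before the data were examined, the epithelial adhesion genes stood highest in the USP22 comparison. All 16 had a positive ratio in the authors' deposited table, with a median of 0.72, and 3 were called higher, OVOL1 (1.25), ST14 (1.16) and RAB25 (1.15), with 3 adjusted over the list alone. The camera test of limma gave this list an adjusted p of 3.56e-06, and level-matched random lists had medians between -0.16 and 0.38 in 95% of draws. Of 37 oestrogen receptor targets and luminal genes, 35 were positive, 2 were called higher (OLFM1, 1.27, and SPDEF, 0.98), also when adjusted over the list alone, and the median was 0.54 in the authors' deposited table (camera adjusted p = 3.19e-06). The 20 mesenchymal and fibroblast genes had a median of -0.64 in the authors' deposited table (camera adjusted p = 0.00052), and 3 were called lower, PDGFRA (-1.63), the cadherin CDH2 (-1.33) and ZEB2 (-1.16), with 4 lower when adjusted over the list alone. Genes in the regions of chromosomes 17 and 20 that are amplified in MCF7 had a median of 0.66, 27 of 28 being positive in the authors' deposited table (camera adjusted p = 7.71e-09), with TBX2 called higher (1.31) and 5 higher when adjusted over the list alone. The 28 genes, 14 on each chromosome, share copy number within a region, so they are not independent and this p-value may be too small. No library without immunoprecipitation is among the 10, so copy number and H2Bub cannot be separated at these genes.

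Several lists of widely expressed genes were also above other genes in the USP22 comparison without a called member. The medians in the authors' deposited table were 0.48 for 71 cytosolic ribosomal protein genes (camera adjusted p = 1.08e-06), 0.54 for 28 housekeeping genes (1.59e-05), 0.39 for 32 G2/M genes (9.26e-05) and 0.30 for 41 oxidative phosphorylation genes (0.000295). The 20 immediate early genes had a median of 0.54 in the authors' deposited table, with JUNB called higher (1.42) and ATF3 lower (-1.16), and a camera adjusted p of 0.0147 (0.0765 with a correlation of 0.05 between genes). Called members of other lists in the authors' deposited table were CEBPB (1.78), ITGB4 (1.16), BCL2 (-1.04), FLT1 (-1.31), USP44 (-1.55), HOXD3 (-1.62), ACTN2 (-1.85), RYR2 (-1.30), HERC5 (-1.26) and IFI44L (-2.10). Immune cell genes had a median of -0.63, 16 of 20 being negative (camera adjusted p = 0.0399), and silent tissue-specific genes one of -0.49, 26 of 33 being negative (0.018), in the authors' deposited table; neither passed with a correlation of 0.05 between genes (adjusted p = 0.126 and 0.110). Of the calls named for this comparison, 6 ended when the ratios were centred by 0.03, those of OVOL1, ST14, RAB25, SPDEF, TBX2 and ATXN7L2 (adjusted p between 0.0501 and 0.0634), and 11 when the trend with mean score was removed, those 6 with ADRM1, LOC100128338, NPEPL1, ITGB4 and HOXD3. With the running median of neighbouring genes subtracted, 24 ended, CACNG4, EVPL, OLFM1, PDGFRA and CDH2 among them. The 38 HOX genes had a median of -0.47 in the authors' deposited table, with 1 called lower and none adjusted over the list alone, and a camera adjusted p of 0.0168 (0.11 with a correlation of 0.05 between genes and 0.354 with the trend removed), and the median lay inside the range of level-matched lists (-0.49 to 0.10). CDKN2A had a ratio of -1.08 and did not pass (adjusted p = 0.117 in the authors' deposited table). In all, 19 of 28 lists passed the set test and 12 of these also lay outside the range of level-matched lists. With a correlation of 0.05 between genes in place of 0.01, 8 of the 19 passed. An estimated correlation needs values per library and could not be used.

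In the comparison for USP27x, HOX and mesenchymal genes were lower, and luminal, amplicon and interferon response genes higher. The authors' deposited table called 2039 genes, 1470 lower and 569 higher. LDHB, the B subunit of lactate dehydrogenase, had the most negative log2 ratio among well-covered genes (-3.10, adjusted p = 3.91e-07 in the authors' deposited table). It was followed in the authors' deposited table by the calponin CNN3 (-2.98), SLFN11 (-2.85), the phosphodiesterase PDE10A (-2.83), SAMD5 (-2.82), the let-7 antagonist LIN28B (-2.75), the gap junction gene GJA1 (-2.75) and the neuronal RNA-binding gene ELAVL2 (-2.72, adjusted p = 1.02e-08). The largest increases among well-covered genes were at RAMP3, a receptor activity-modifying protein (2.37, adjusted p = 4.51e-08 in the authors' deposited table), HELZ2 (1.84), LOC100130264 (1.76), the ion exchanger SLC24A3 (1.66, adjusted p = 3.83e-11), DOK7 (1.62), PRR15L (1.53) and RET (1.49).

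HOX genes had the most negative list median of the USP27x comparison. Of 38 measured, 13 were called lower and none higher in the authors' deposited table, with a median of -1.12, and 19 were lower when p was adjusted over the list alone. HOXB5 (-2.33), HOXB13 (-2.22), HOXD10 (-2.15) and HOXB3 (-2.09, adjusted p = 1.2e-06) led in the authors' deposited table. The camera adjusted p of the list was 5e-08. It was 0.000591 with a correlation of 0.05 between genes, and 0.00886 with the trend with mean score removed as well. HOX genes lie in clusters and are not independent, so these p-values may be too small. Of 20 mesenchymal and fibroblast genes, 6 were lower in the authors' deposited table and 7 adjusted over the list alone (1 higher), among them CDH2 (-2.47, adjusted p = 5.03e-10), vimentin (VIM, -1.99), ZEB1 (-1.98) and ZEB2 (-1.89). The median of that list was -0.67 in the authors' deposited table (camera adjusted p = 3.31e-05). CDKN2A, the cyclin-dependent kinase inhibitor gene that is commonly reported as lost in MCF7, was also called lower (-2.23, adjusted p = 4.4e-07 in the authors' deposited table). If these cells lack the gene, that ratio cannot be a change of H2Bub in them. Whether they carry it was not tested. The mean score of CDKN2A was above the median of all genes (12.9). Of 33 tissue-specific genes chosen as silent in breast epithelium, 6 were lower in the authors' deposited table, including ACTN2 (-2.18), RYR2 (-1.87) and PAX6 (-1.63), and 6 adjusted over the list alone. The camera adjusted p of this list was 0.00547, and 0.0787 with a correlation of 0.05 between genes or 0.130 with the trend removed.

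Luminal genes, genes of the MCF7 amplicons and interferon response genes were higher in the USP27x comparison. Of 28 amplicon genes all had a positive ratio in the authors' deposited table, 11 were called (19 adjusted over the list alone) and the median was 0.67 (camera adjusted p = 8.02e-11), against -0.02 to 0.26 for level-matched lists. Genes of an amplicon share copy number and are not independent, so this p-value may be too small. Copy number and H2Bub could not be separated at them. SULF2 (1.14), HEATR6 (1.08), TBX2 (1.04) and CA4 (1.02) were the largest called in the authors' deposited table. Among 37 oestrogen receptor targets and luminal genes 7 were called higher (8 adjusted over the list alone) and none lower in the authors' deposited table, with a median of 0.46 and a camera adjusted p of 3.14e-07. They included GREB1 (adjusted p = 1.87e-06 in the authors' deposited table), OLFM1 (1.26) and the progesterone receptor gene PGR (1.22). Epithelial adhesion genes had a median of 0.65, with CLDN3 (1.12), the E-cadherin gene CDH1 (0.80) and ESRP1 (0.65) called in the authors' deposited table and 9 adjusted over the list alone (camera adjusted p = 3.71e-05). Of 24 interferon response genes, 4 were called higher in the authors' deposited table, IRF9 (2.09, adjusted p = 1.65e-06), OAS1 (1.62), OAS3 (1.18) and STAT1 (0.93), and 6 adjusted over the list alone, with a median of 0.41 and a camera adjusted p of 0.00224. The same list had a median of -0.38 in the authors' deposited shUSP22 table, where 2 members were lower. That median lay inside the range of level-matched lists (-0.51 to 0.22), and the list did not pass there (camera adjusted p = 0.0908). The difference between the 2 knockdowns was not tested.

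Called genes in the remaining lists of the USP27x comparison went both ways. ICAM1 (1.19) and BCL3 (0.92) of the NF-kB list, BCL2L1 (0.76) and CFLAR (0.73) of the apoptosis list and FOS (1.14), JUNB (1.03) and KLF4 (0.98) of the immediate early list were higher in the authors' deposited table. The serine synthesis gene PSAT1 (-1.81), ATF3 (-1.18), USP44 (-1.59), SUPT3H (-0.81), ELL2 (-0.72), EGFR (-0.91) and FLT1 (-0.88) were lower in the authors' deposited table. Of 20 olfactory receptor genes, 4 were called lower there and none higher (OR51E2, OR51E1, OR51B5 and OR8U8), with 5 lower adjusted over the list alone. That list did not pass (camera adjusted p = 0.141), and with the neighbours' running median subtracted none of these calls stayed. No member of the ribosomal protein, housekeeping, oxidative phosphorylation, G2/M, p53 target or immune cell lists was called in the shUSP27x table. In all, 8 of 28 lists passed the set test, 8 of these lay outside the range of level-matched lists, and 6 passed with a correlation of 0.05 between genes. Of the calls named for this comparison, 3 ended on centring (CHAF1A, ALB and OR8U8), 14 with the trend with mean score removed, among them ATXN7, CDH1, ESRP1, SULF2, CA4, JUNB, KLF4 and BCL2L1, and 21 with the neighbours' running median subtracted, among them CLDN3, HEATR6, TBX2, FOS, ATF3, SUPT3H and FLT1.

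**Figure D1:**
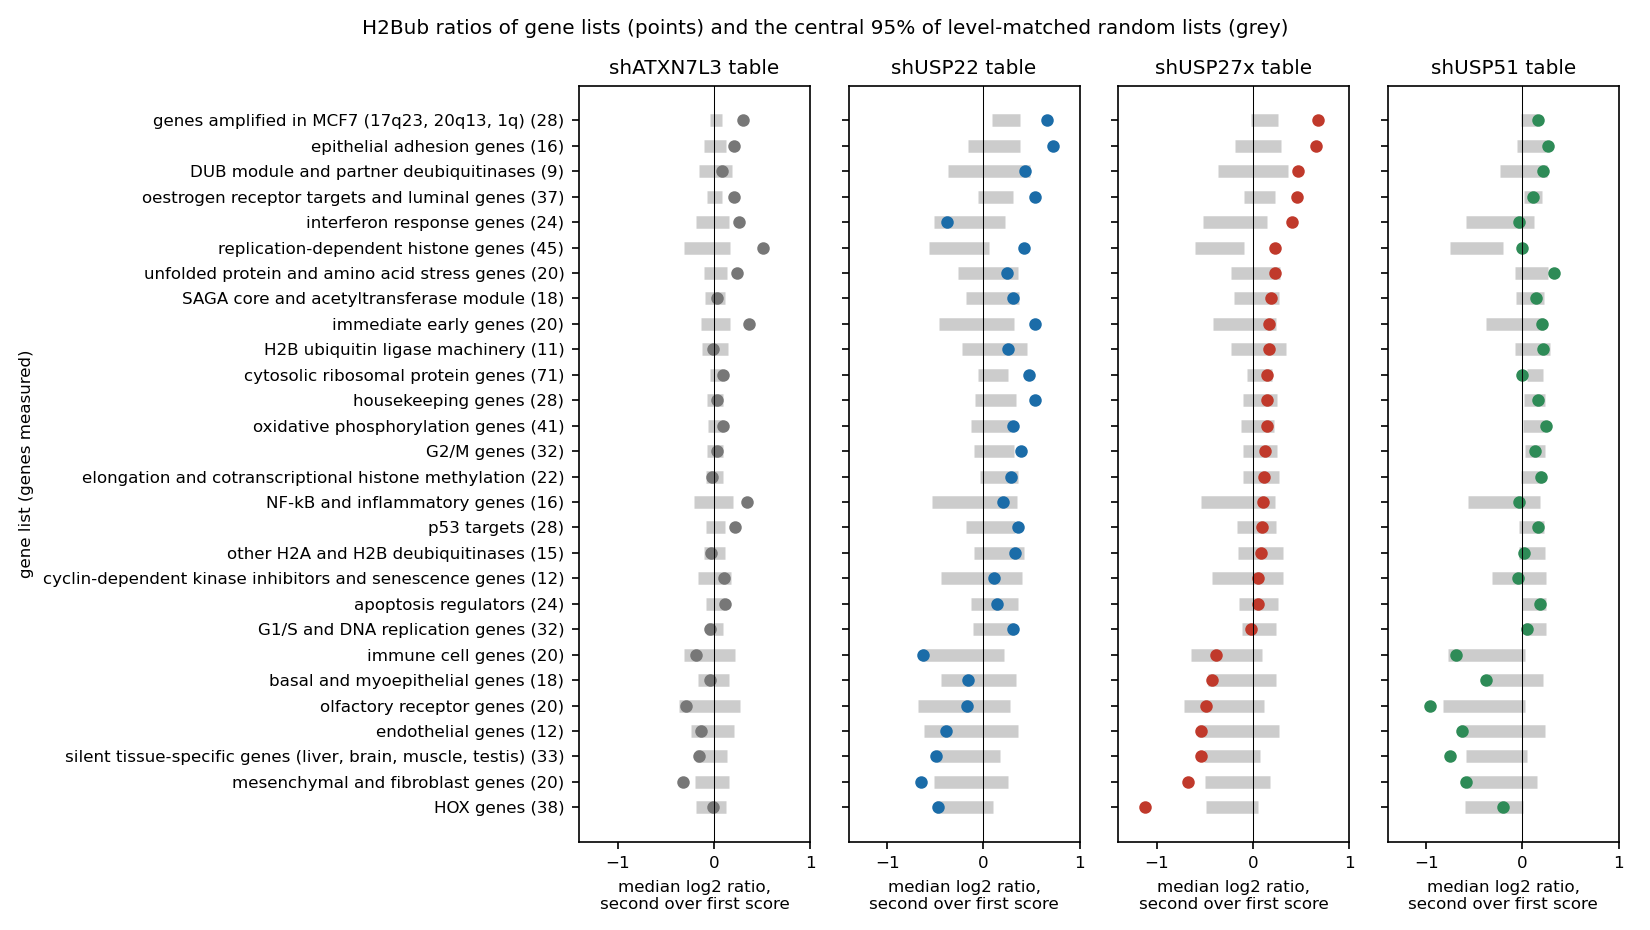
Median log2 ratio (second over first score, horizontal axis) of each of 28 gene lists in the 4 deposited tables, with the number of genes measured beside each list name (vertical axis). Points are the list medians and grey bars the central 95% of medians of 10000 random lists matched on mean score; the HOX genes stand at -1.12 and the amplified genes at 0.67 in the shUSP27x panel.

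In the comparison for USP51, few genes passed, and most of those were lower, though less so with the signal of neighbouring genes subtracted. The authors' deposited table called 136 genes, 126 lower and 10 higher. The named decreases in the authors' deposited table were the acid-sensing channel gene ASIC2 (-1.43, adjusted p = 0.0281), the adhesion genes OPCML (-1.41) and CNTN5 (-1.39, adjusted p = 0.0182), FGF14 (-1.36), CSMD1 (-1.36), LOC283867 (-1.43), ANO3 (-1.35) and LOC100506403 (-1.34). The named increases were the receptor tyrosine kinase gene FGFR3 (1.07, adjusted p = 0.0446 in the authors' deposited table), FAM46C (1.06), SYT7 (1.03), ZNF213 (1.01), NUAK2 (0.97), ZBTB46 (0.94) and NPRL3 (0.79). Subtracting the median ratio of 0.02 gave 292 genes (16 higher, 276 lower), subtracting the running median of neighbouring genes gave 229 (88 higher, 141 lower), and removing the trend of the ratio with mean score gave 430 (39 higher, 391 lower). The calls of NUAK2, ZBTB46 and NPRL3 ended with the trend removed, and those of FGFR3, ZNF213, ZBTB46, NPRL3 and OPCML with the neighbours' running median subtracted.

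Lists of genes that luminal cells do not use were low in the USP51 comparison. Median log2 ratios in the authors' deposited table were -0.96 for 20 olfactory receptor genes (camera adjusted p = 0.000386), -0.75 for 33 silent tissue-specific genes (3.62e-05), -0.69 for 20 immune cell genes (0.000141), -0.63 for 12 endothelial genes (0.0101) and -0.58 for 20 mesenchymal genes (0.000386). Only OR51B5 (-1.55), OR8U8 (-1.30) and the glutamate receptor gene GRIN2A (-1.17) of these lists were called in the authors' deposited table. The medians of the immune cell and endothelial lists lay inside the ranges of level-matched lists (-0.78 to 0.02 and -0.64 to 0.23), and those of the olfactory receptor, silent tissue-specific and mesenchymal lists below theirs (-0.83, -0.59 and -0.57 at the lower end). With the trend with mean score removed, the olfactory receptor and immune cell lists no longer passed (adjusted p = 0.0851 and 0.0506). When p was adjusted over each list alone, 7 olfactory receptor, 1 silent tissue-specific, 4 immune cell, 4 endothelial and 3 mesenchymal genes were lower. Stress genes of the unfolded protein and amino acid response had a median of 0.33 (camera adjusted p = 0.000985) and 41 oxidative phosphorylation genes one of 0.25 (0.000141), with no member called in the authors' deposited table. All 16 epithelial adhesion genes were positive in the authors' deposited table, with a median of 0.26 above the range of level-matched lists (-0.05 to 0.24) and a camera adjusted p of 0.0103 (0.0558 with a correlation of 0.05 between genes, 0.0851 with the trend removed). Of 28 amplicon genes, 22 were positive in the authors' deposited table, with a median of 0.16 above the range of level-matched lists (-0.01 to 0.15) and a camera adjusted p of 0.0387 (0.171 and 0.356 under the same changes). The luminal list had a median of 0.11 in the authors' deposited table and did not pass (camera adjusted p = 0.0633), nor did the HOX list (-0.20, 0.41). In all, 14 of 28 lists passed, 7 of these outside the range of level-matched lists, and 7 passed with a correlation of 0.05 between genes.

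**Figure D2:**
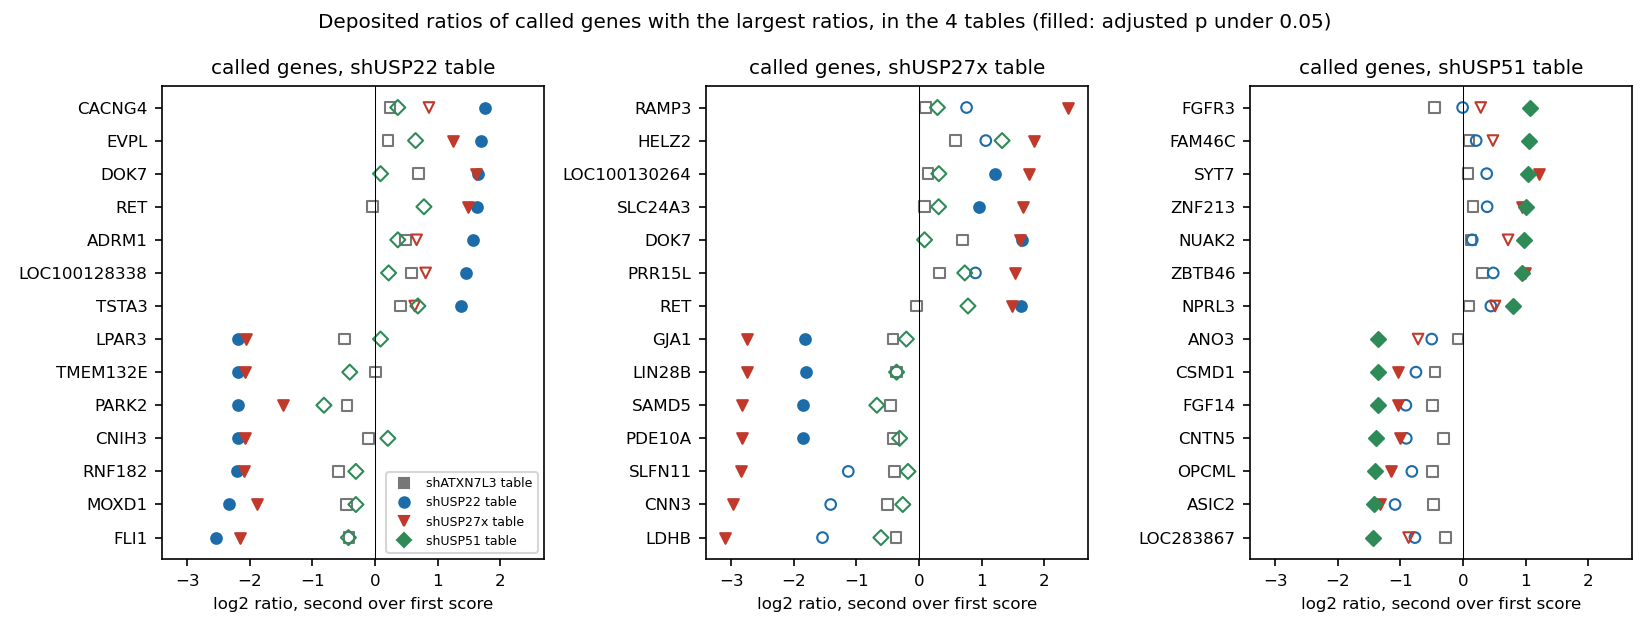
Deposited log2 ratios (horizontal axis) of called genes of each shUSP table, up to 7 with the largest ratio each way among those with a mean score above the median (vertical axis), drawn for all 4 tables by marker shape and colour; filled markers have an adjusted p under 0.05. LDHB lies at -3.10 and RAMP3 at 2.37 in the shUSP27x table.

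The comparison for ATXN7L3 had 1 shATXN7L3 library, and its low ratios were those of 1 library on each side, so it had no replicate check. The authors' deposited table held no gene with an adjusted p under 0.05 from edgeR, and 54 genes had an unadjusted p under 0.05. Far more genes than that would fall under 0.05 by chance, so these p-values, with no replicate behind them, are not calibrated. The quartiles of all ratios in the authors' deposited table were -0.19 and 0.18. Without a test, the largest ratios among well-covered genes of the authors' deposited table were at S100A11 (1.06), SOGA3 (1.05), PHF21B (0.99), C16orf45 (0.99), ARRDC3 (0.86) and the stress-induced phosphatase subunit PPP1R15A (0.85). Among the lowest of the well-covered genes in the authors' deposited table were ALX4 (-0.93), RAMP1 (-0.89), CELF2-AS2 (-0.88), ZNF532 (-0.79), ZNF717 (-0.78) and JAM3 (-0.76). As a description of these libraries, 12 of 28 list medians lay outside the central 95% of level-matched random lists. The replication-dependent histone genes were highest at 0.51 in the authors' deposited table, but these genes are short and near-identical and their scores were low, with a median of 0.712. Immediate early genes (0.37), NF-kB and inflammatory genes (0.34), amplicon genes (0.31), interferon response genes (0.27), stress genes (0.25), p53 targets (0.22), luminal genes (0.21), epithelial adhesion genes (0.21), apoptosis regulators (0.12) and ribosomal protein genes (0.09) had medians above the central 95% of their random lists in the authors' deposited table. Mesenchymal genes (-0.32) lay below the range, and the HOX genes (-0.01) inside it.

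The genes called for USP22 and USP27x overlapped. Of the 866 genes lower in the authors' deposited shUSP22 table, 700 were also lower in that for shUSP27x, where 60.9 would be shared by independent lists of these sizes. Of the 122 higher, 54 were shared against 3.32, and no gene was called in opposite directions. The USP27x and USP51 tables, whose low ratios correlated most, shared 43 lower genes against 8.87 and 6 higher genes against 0.272. The USP22 and USP51 tables shared 3 lower genes against 5.22 and no higher gene. The genes GAS7 and GPC5, picked out after their values were seen, were the 2 called lower in all 3 of the authors' deposited tables.

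Across genes, which are not independent replicates, the log2 ratios of the authors' deposited tables for shUSP22 and shUSP27x had a Pearson correlation of 0.704 and a covariance of 0.323. Unchanged groups set against 1 shared control, simulated with errors implied by the deposited p-values, gave 0.501 and 0.103. The 0.501 follows from giving the control as much of each variance as the group. A shared control was seen only for shATXN7L3 with shUSP22 and is an assumption for every other pair. The shUSP22 first side was that of shATXN7L3, on whose reads the shUSP27x and shUSP51 ratios had slopes of only -0.18. For pairs that do not share a control the simulated values are too high. The correlation was 0.662 for shUSP27x with shUSP51 (covariance 0.248, simulated 0.0809) and 0.537 for shUSP22 with shUSP51 (covariance 0.213, simulated 0.102). For shATXN7L3 with shUSP22, which share a first side, it was 0.497 and the covariance was 0.155 against a simulated 0.160; among genes with a mean score above the median these were 0.0660 and 0.0543. For shATXN7L3 with shUSP27x the correlation was 0.325 and the covariance 0.0958 against a simulated 0.127 (0.0730 and 0.0437 above the median score), and with shUSP51 it was 0.282 and 0.0716 against 0.126 (0.0261 and 0.0437). The p-values of the shATXN7L3 table were too large for a calibrated test, so the errors implied by them are too wide. The simulated covariances of its pairs are then too high, and a value at or below them does not show that a shared control explains it. The controls could not be split. Part of the correlation of shATXN7L3 with shUSP22, and of the overlap and correlation of shUSP27x with shUSP51, may therefore come from shared control libraries. For the other pairs the slopes of -0.18 go against a wholly common control but do not exclude a partly shared one.

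H2Bub ratios followed the mean score in all 3 shUSP tables. In the lowest decile of genes by mean score the median log2 ratios of the authors' deposited tables were -0.27 for shUSP22, -0.40 for shUSP27x and -0.52 for shUSP51, and in the eighth decile they were 0.13, 0.09 and 0.15. For shATXN7L3 these medians were -0.09 and 0.00 in the authors' deposited table. The median mean score was 270 for the amplicon genes, 49.5 for the luminal genes, 38.7 for the housekeeping genes, 4.18 for the mesenchymal genes, 2.51 for the HOX genes and 0.576 for the olfactory receptor genes, against 12.9 over all genes. Ratios of lists with low scores therefore rest on few reads, and the level-matched random lists are the comparison given for them.

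**Figure D3:**
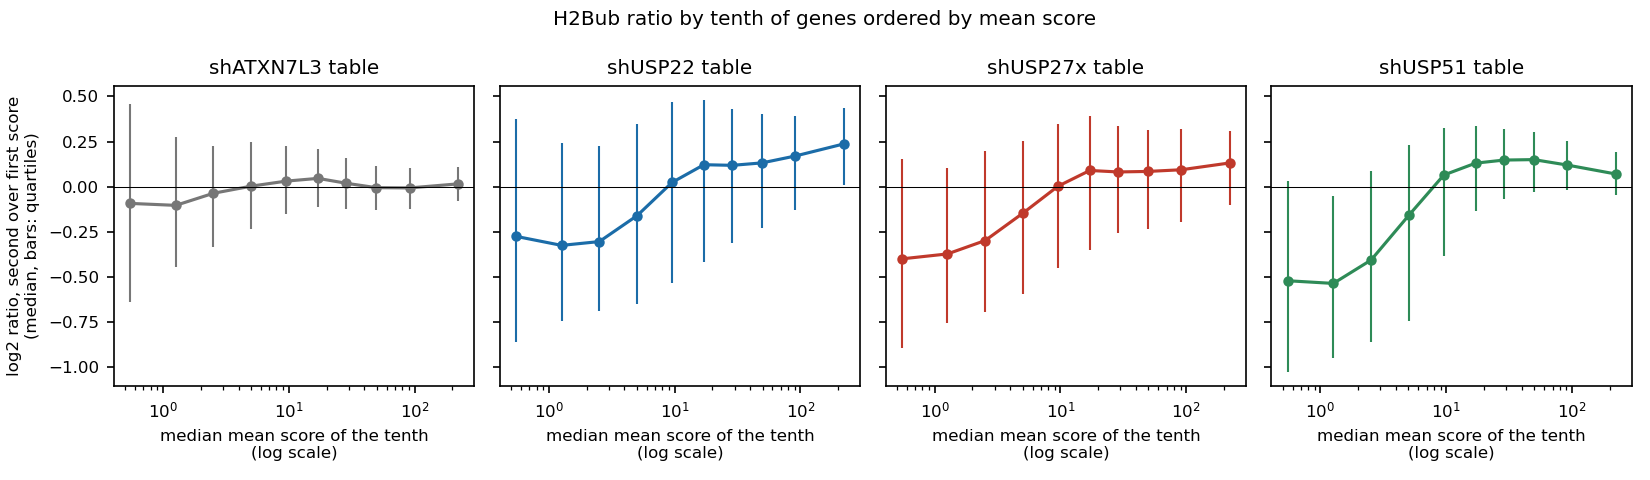
Median log2 ratio (vertical axis) of each decile of the 20891 genes ordered by mean score (horizontal axis, log scale) in the 4 deposited tables; bars span the quartiles. In the shUSP51 panel the median goes from -0.52 in the lowest decile to 0.15 in the eighth.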

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

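For counts of genes, the stricter threshold, the level filter and the neighbour subtraction were planned before the data were examined; all other settings were chosen after seeing the data. An adjusted p under 0.01 left 435 of 988 genes in the shUSP22 table, 1090 of 2039 in shUSP27x and 6 of 136 in shUSP51, as a stricter threshold must leave fewer. The other settings gave 688 to 1046 genes for shUSP22 and 1430 to 1973 for shUSP27x, within 1.5 times the main counts. Like counts did not mean the same genes. With the running median of neighbouring genes subtracted, 516 of 958 shUSP22 and 1092 of 1968 shUSP27x genes stayed called. The higher genes of shUSP22 went from 122 to 78 on centring and 74 with the trend removed. The shUSP51 count was not stable, with 229 genes once the running median of neighbouring genes was subtracted, 292 after centring and 430 once the trend with mean score was removed; 75 of 117, 136 of 136 and 115 of 136 of its genes stayed called, and the cause was not tested. Lower genes were 92.6% of calls in shUSP51 and 61.6% after the neighbour subtraction, with 10 higher genes against 88, and 39 with the trend removed. The adjusted p of OR8U8 became 1 in both the shUSP27x and shUSP51 tables with the opposite sign under that subtraction. With a correlation of 0.05 between genes, 8 of 19 lists passed for shUSP22 and 7 of 14 for shUSP51, and with the level trend removed 10 of the 19 and 5 of the 14 passed, and 6 of 8 for shUSP27x, with the histone list newly called in shUSP51 and shUSP27x (6 and 7 in all), the cause not being tested; no called list changed direction. The correlation of shATXN7L3 with shUSP27x ratios went from 0.325 to 0.626 among genes with a mean score above the median, where ratios are less noisy. No paired analysis was possible because the tables hold no values per library, so no replicate block could be fitted. For the same reason the planned other scalings, count filters, DESeq2, fits on fewer libraries, prior counts and pseudocounts, leaving out single libraries, the pLKO control for ATXN7L3 and an estimated correlation between list genes were not run. Direct contrasts between knockdowns and a fit of all 10 libraries for ATXN7L3 were not run either. Of the named gene results, 50 were no longer called and 2 reversed with neighbours subtracted, 28 were no longer called with the trend removed and 9 on centring. Depth limits the low rows, where a mean score of 1 stands for about 15.2 reads.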

Other observations

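All tests in this part, and the bounds that decide them, were chosen after the results were seen. The bound on the share of higher genes was changed to a Wilson bound once its value was known, which moved that test from excluding the explanation to leaving it open, and the tests of the shared first side and of the shUSP51 pattern were rewritten likewise. At C9orf53, which lies beside CDKN2A and was picked out after its value was seen, the authors' deposited shUSP27x table gave a log2 ratio of -5.28 at a mean score of 0.265 (adjusted p = 0.0874), and the shUSP22 table gave -2.58 (adjusted p = 0.0434). The replication-dependent histone genes, whose near-identical copies share reads, had medians of 0.42 in the authors' deposited shUSP22 table and 0.23 in that for shUSP27x, above the ranges of level-matched lists (-0.56 to 0.05 and -0.60 to -0.09), with no gene called. Ribosomal protein genes had a median of 0.48 in the authors' deposited shUSP22 table and -0.01 in the shUSP51 table, below the 0.05 to 0.21 of level-matched lists; the difference between these tables was not tested.

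The first pattern is that mesenchymal signal was lower and luminal, epithelial and amplicon signal higher in the shUSP22 and shUSP27x tables, with HOX signal lower in the shUSP27x table; the mesenchymal, epithelial and amplified medians lay outside their matched ranges in the same directions in the shUSP51 and shATXN7L3 tables, as did the luminal median in the latter. The ratios argue against a regional change of copy number as the whole cause of the lower genes, but leave a regional part open. In the shUSP27x table, genes 5 to 10 places from a lower gene had a median log2 ratio of -0.16 where the lower genes themselves had -1.34. Of these neighbours 10.8% were called lower, against 7.13% of all placed genes. The 9089 neighbours were pooled with each position counted once, so lower genes lying close together counted for less than isolated ones. With the running median of neighbouring genes subtracted, 961 genes were lower in the shUSP27x comparison in place of 1470. Neighbours of higher genes had 0.19 against 0.88 in that table and 0.38 against 1.18 in the shUSP22 table. A regional part therefore stays open for the higher genes too. Chromatin of other cells in the first side that the shATXN7L3 and shUSP22 tables share would give both like ratios. Yet amplicon genes stood 0.39 higher in the shUSP22 table (95% bootstrap interval 0.27 to 0.51) and mesenchymal genes differed by -0.41 (-0.56 to -0.11). The intervals were drawn over genes, and amplicon genes are not independent, so theirs may be too narrow. This explanation stays open because the shATXN7L3 side is 1 library, which may hold such chromatin itself. As the whole source of the higher genes of the shUSP27x table, such chromatin stays open too. The upper quartile of the amplified list was 0.74. Of 569 genes, 5.62% (95% Wilson interval 4.01 to 7.83), MIR2964A and RAMP3 among them, exceeded it by more than their implied 95% error. At most 2.5% was set as allowed and a lower bound above 5% as excluding it. The share cannot decide, because those 569 genes were picked by the same ratios and p-values. Nor need that quartile be the most that such chromatin can give. Signal on the first side at CDKN2A and C9orf53 would go with such chromatin if these cells lack that locus, which was not tested. The knockdown itself cannot be told apart from the libraries of each table, with 1 cell line and 1 table per target, and the amplified list stood at 0.16 in the shUSP51 table, smaller but above its matched range.

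The second pattern is that silent and tissue-foreign genes were lower in the shUSP51 table. The tables argue against a few genes taking most of the reads, which would shift the rest alike, since the eighth decile of genes by mean score stood 0.67 above the lowest. The trend with mean score as the whole cause stays open: the silent tissue-specific (-0.75) and olfactory receptor (-0.96) medians lay below their level-matched ranges, which goes against it, but only 2 of the 4 silent lists passed the set test once it was removed, without the olfactory receptor list, and none with a correlation of 0.05 between genes as well (adjusted p between 0.179 and 0.245). Stronger enrichment over background in the knockdown libraries stays open, because the medians of these lists lay below 0 within 0.32 of each other but did so within 0.16 in the shUSP27x table and 0.46 in the shUSP22 table too. A loss of H2Bub at silent genes through USP51 knockdown would look alike and was not tested.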
